A study of Rattus norvegicus with 6 samples.

How the data were processed

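Chromosome conformation capture with a single viewpoint (4C-seq) was carried out on cardiac endothelial cells of rats, with a gene promoter on chromosome 13 as the viewpoint. In 4C-seq, chromatin is fixed, cut with a restriction enzyme and re-ligated, and the fragments joined to the viewpoint are amplified and sequenced. Per the labels' protocols, the enzyme was EcoRI, the cells were at passage 2, cells of both sexes were pooled, and fixation used 2% formaldehyde for 10 min. There were 6 libraries, 3 from each of 2 strains. The Dahl salt-sensitive strain is called SS. The consomic strain called SS13BN carries chromosome 13 of the Brown Norway (BN) rat on the SS background. The labels do not say that the libraries of a strain came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

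The authors deposited 1 table per library, with 1 score per restriction fragment. Per the submitters' processing notes, the genome build was rn5 and CASAVA 1.8 was used. The aligner, the read filters and the program that made the scores are not given in the sources used here. The tables cover chromosomes 1 to 20 and X. Intervals of the tables are contiguous and closed, the first starts at 0, and coordinates are given below as the tables give them, so they may lie 1 base from a genome browser's.

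The way the deposited scores were made was worked out from their values. On the 20 chromosomes other than 13, every score equalled (k - Wp) divided by the square root of Wp(1 - p). Here k is the number of captured fragments in a running window of W = 501 fragments and p is the captured share of that chromosome. A captured fragment is one with at least 1 read. Solving these equations gave a captured or not captured state for each of 759990 fragments, and the states rebuilt 100.0% of the windows in each library. On chromosome 13 far from the viewpoint, the window was 37 fragments and the background 3000 fragments, and 100.0% of the windows were rebuilt. Between 52028242 and 58275224 on chromosome 13, the score was a captured fragment's read number minus the mean, divided by the SD, over captured fragments. Whole reads were recovered there on the assumption that the lowest captured fragment had 1 read. Neighbouring fragments without reads were merged in the tables into 1 row listed at 0.

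Chromosome 13 was listed at 0 throughout in SS 3 and SS13BN 3. Comparisons on chromosome 13 therefore rest on 2 libraries per strain, and those on other chromosomes on 3. In SS13BN 2, the score of 1 fragment was 14.0 too low for the scores to sum to 0. The shifted value, 9727 reads in place of 4792, was used, and the results with the listed value are among the alternatives. The fragment that holds the viewpoint, from 55560539 to 55570180, was listed at 0. The viewpoint position was taken as 55570181, the start of the fragment with the highest median reads.

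The tests were fixed before the data were examined for count tables. The tables hold scores, so the count-based tests planned first were replaced by the planned fallback. This was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(value + 1), where the value was scaled to the mean library total. Values were captured fragments in 50 kb windows of chromosome 13 and in 500 kb windows of other chromosomes, captured fragments per chromosome, and reads per fragment within 1 Mb of the viewpoint. Windows needed a mean of at least 1, and fragments within 10 kb of the viewpoint were left out of chromosome 13 windows. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Half-widths of 95% intervals are SE times limma's t quantile. A fold on this scale understates the change of low values. Shares were compared with exact two-sided permutation tests, whose smallest p is 0.333 for 2 against 2 libraries.

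Contact windows on chromosome 13 were 50 kb windows whose residual from a lowess fit of log2(captured + 1) on log10 distance exceeded 2 scaled median absolute deviations in each scored library of a strain. The lowess fraction was 0.3, and the curve was fitted on absolute distance with both sides of the viewpoint pooled. Contact windows on other chromosomes were 500 kb windows with more captured fragments than the library's overall share gives, by an exact one-sided binomial test with a Benjamini-Hochberg adjusted p under 0.05 in all 3 libraries of a strain. Chance overlap was taken as the product of both counts divided by the number of windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used, and plots were drawn with matplotlib 3.10.9.

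Windows were named by a rule fixed before the data were examined. It names the viewpoint window and the 5 other windows of chromosome 13 with the highest mean capture. It names up to 5 higher and 5 lower windows or fragments past the threshold with separated strains, or the 3 with the smallest p where none passed. It also names up to 10 contact windows per strain and up to 5 of one strain alone, by smallest median p. Gene coordinates of rn5 were not used here, so windows carry no gene names and the planned gene lists were not analysed here.

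Steps were tested on simulated data. For chromosomes other than 13, the capture states were recovered for 100.0% of simulated fragments. For chromosome 13 far from the viewpoint, the true window and background counts were among the solutions for 100.0% of simulated fragments. The step from these counts to capture states, and the recovery of reads near the viewpoint, were not simulated. With 200 of the 500 kb windows changed, limma called 5.00% of those changed 1.5-fold, 54.0% of those changed 2-fold and 94.5% of those changed 3-fold. With 200 of the 50 kb windows of chromosome 13 changed 4-fold in 2 against 2 libraries, it called 0. With 111 near-viewpoint fragments changed, it called 3.60% at 2-fold, 53.2% at 4-fold and 93.7% at 8-fold. Contact windows raised 2-fold and 3-fold on other chromosomes were found in both strains in 13.0% and 99.0% of cases. On chromosome 13, 0 of 50 windows raised 2-fold, 16.0% of those raised 3-fold and 42.0% of those raised 4-fold were found in both strains. Each simulation of chromosome 13 also gave 5 to 8 false contact windows in either strain, and those of other chromosomes gave 0. The latter drew every unraised window at the library's overall share, which is what the binomial test assumes. Their 0 therefore cannot show how many false windows arise where capture varies with fragment length or chromosome.

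Depth is the number of captured fragments. It ran from 66610 to 132426 of 759990 on other chromosomes and from 6538 to 9414 of 34455 on chromosome 13. Shares of single libraries carry 95% Wilson intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Alternatives fixed in advance were a replicate block, each library left out, other window sizes, filters, scalings and distance limits, and other thresholds for contact windows. Median-centred values, log odds of capture, mean deposited scores, expectations by fragment length or by chromosome, and the listed value of the SS13BN 2 fragment, or its removal, were added after seeing the data. So were contact windows in 1 of 2 libraries or with each library left out, replicate agreement at 1 Mb and 200 kb, and every alternative for near-region reads within 1 Mb.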

Results

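The contacts of 1 gene promoter on chromosome 13 were mapped genome-wide by 4C-seq in cardiac endothelial cells of SS rats and of SS13BN rats, which carry a BN chromosome 13. The design asked where the promoter makes contacts and whether the origin of chromosome 13 alters them. In SS13BN rats the promoter and all its surroundings on chromosome 13 come from the BN rat, and the other chromosomes come from the SS rat.

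Each library captured between 8.76% and 17.4% of the 759990 EcoRI fragments outside chromosome 13. The captured shares were 12.3% (95% Wilson interval 12.3% to 12.4%) in SS 1, 9.99% (9.93% to 10.1%) in SS 2 and 11.9% (11.8% to 12.0%) in SS 3. They were 9.92% (9.85% to 9.98%) in SS13BN 1, 17.4% (17.3% to 17.5%) in SS13BN 2 and 8.76% (8.70% to 8.83%) in SS13BN 3. The strain means were 11.4% ± 1.25 (SD, n = 3) for SS and 12.0% ± 4.70 (SD, n = 3) for SS13BN. On chromosome 13, where 2 libraries per strain carried scores, 19.6% ± 0.0123 (SD, n = 2) of 34455 fragments were captured in SS and 23.1% ± 5.90 (SD, n = 2) in SS13BN. Capture on chromosome 13 was 1.59 times that of the other chromosomes in SS 1, 1.96 times in SS 2, 1.91 times in SS13BN 1 and 1.57 times in SS13BN 2. Reads recovered near the viewpoint numbered 188896 in SS 1, 370560 in SS 2, 181000 in SS13BN 1 and 144406 in SS13BN 2.

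The promoter had 2 zones of dense contact within 1 Mb, one at the viewpoint and one 0.4 to 0.7 Mb towards lower coordinates, in all 4 scored libraries. The distant zone, rn5 chromosome 13 from 54870181 to 55170181, held 25.2% ± 3.23 (SD, n = 4) of the region's reads. The stretch between it and the viewpoint, from 55170181 to 55470181, is as long and held 17.7% ± 1.44 (SD, n = 4). Mean reads per fragment in the distant zone were 2.41 times those of this stretch in SS 1, 1.63 times in SS 2, 2.08 times in SS13BN 1 and 1.59 times in SS13BN 2. Beyond the zone, from 54670181 to 54870181, the mean fell to 87.0 reads per fragment in SS 1, against 876 in the zone. The corresponding pairs were 312 and 1392 in SS 2, 106 and 755 in SS13BN 1, and 126 and 500 in SS13BN 2. At the mirrored distance of 0.4 to 0.7 Mb towards higher coordinates, only 3.68% ± 0.738 (SD, n = 4) of the reads were found. The bounds of these zones were chosen after the values were seen.

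**Figure D1:**
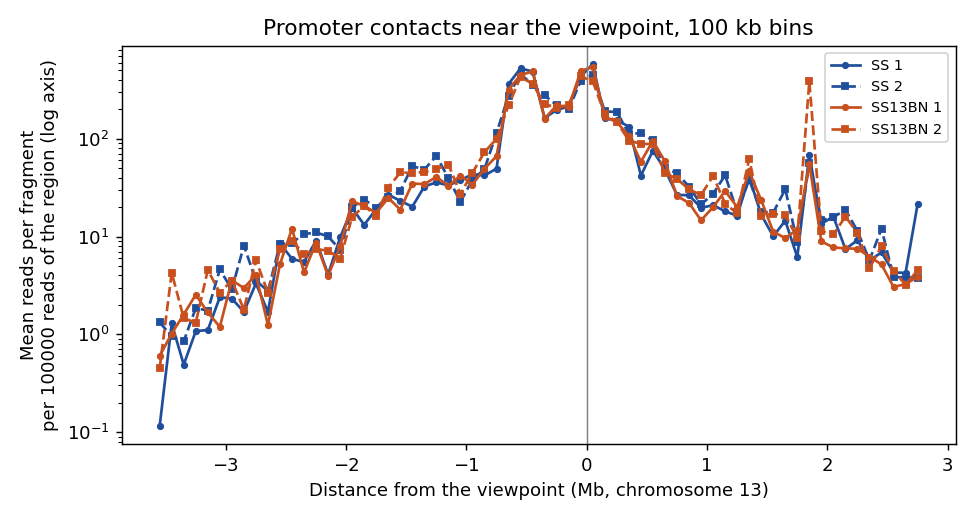
Mean reads per fragment per 100000 reads of the region (log axis) against distance from the viewpoint in Mb, in 100 kb bins, 1 line per library (blue SS, orange SS13BN; solid replicate 1, dashed replicate 2). All 4 lines peak at the viewpoint and again 0.4 to 0.7 Mb below it, and the SS13BN 2 peak near 1.85 Mb comes from 1 fragment.

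The windows of chromosome 13 with the most captured fragments all lay within 2 Mb of the viewpoint. The window that holds the viewpoint, from 55550001 to 55600000, had all 11 of its fragments captured in each scored library. The highest others were the 50 kb windows that start at 54600001, 54050001, 56350001, 55000001 and 55300001, with means of 20.8, 20.5, 16.3, 16.0 and 16.0 captured fragments. Of these, the window at 55000001, inside the distant zone, had the most reads: 17672 in SS 1, 30627 in SS 2, 13530 in SS13BN 1 and 12530 in SS13BN 2. The window at 54600001, with more fragments, had 1400, 2857, 1551 and 1268 reads in the same order.

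Capture was nearly complete to 2 Mb on both sides and then dropped. At 1 to 2 Mb, 98.3% ± 0.609 (SD, n = 4) of fragments were captured on the side of lower coordinates and 96.4% ± 1.17 (SD, n = 4) on the other. At 3 to 5 Mb these were 27.7% ± 4.08 and 27.4% ± 6.19. Farther out, the sides diverged in every scored library. At 5 to 10 Mb, capture on the side of higher coordinates was 0.649, 0.647, 0.665 and 0.721 times that of the side of lower coordinates in SS 1, SS 2, SS13BN 1 and SS13BN 2. At 20 to 40 Mb it was 1.91, 2.05, 2.09 and 1.83 times as high, and the mean share was 24.8% ± 5.40 (SD, n = 4) against 12.7% ± 3.54 (SD, n = 4). The side of lower coordinates at 20 to 40 Mb thus stood at 0.938 to 1.10 times the library's level on other chromosomes. These shares are per fragment and were not adjusted for fragment length, with which capture varied on other chromosomes. The side with the lower share held more fragments, 1577 against 1388 at 5 to 10 Mb and 6771 against 5480 at 20 to 40 Mb. At 40 to 64 Mb it held fewer, 3708 against 5871. How far fragment length enters the contrast between sides was not tested.

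**Figure D2:**
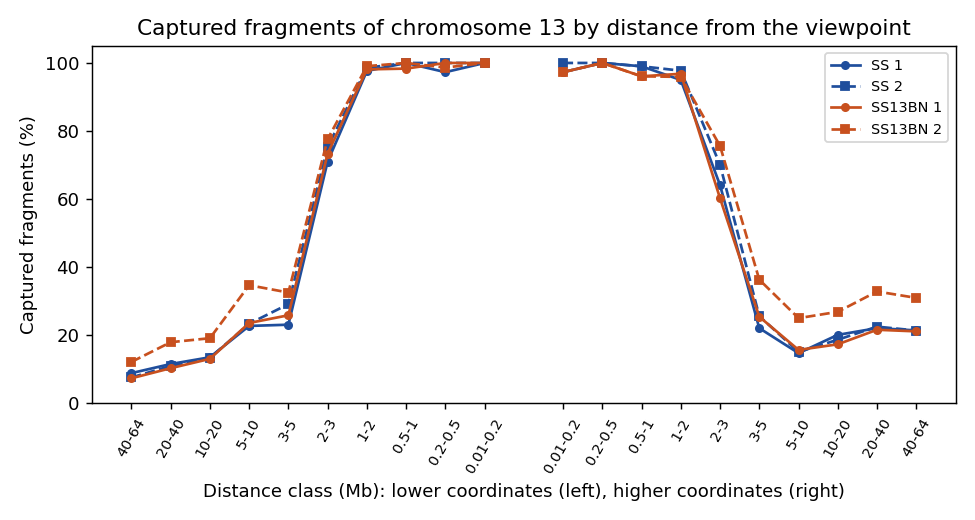
Captured fragments (%) of chromosome 13 by distance class in Mb, lower coordinates on the left and higher coordinates on the right, 1 line per library (blue SS, orange SS13BN; solid replicate 1, dashed replicate 2). Classes differ in width. Every line is near 100% up to 2 Mb, and beyond 10 Mb every library is higher on the right.

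The strains did not differ detectably in the share of captured fragments that lay on chromosome 13. A fragment counts once here, however many reads it had, so this is not a share of reads. It was 6.72% and 6.64% in SS 1 and SS13BN 2, which captured 12.3% and 17.4% of the fragments elsewhere. It was 8.17% and 7.98% in SS 2 and SS13BN 1, which captured fewer, 9.99% and 9.92%. The share was thus lower where more fragments were captured elsewhere, but those captures are part of its denominator. By reads near the viewpoint the order was different, with the most, 370560, in SS 2 and the fewest, 144406, in SS13BN 2. The share of captured fragments on chromosome 13 was 7.44% ± 1.02 (SD, n = 2) in SS and 7.31% ± 0.951 (SD, n = 2) in SS13BN. The difference of -0.132 percentage points had an exact two-sided permutation p of 0.667, and it turned to 0.592 without SS 2 and to 0.541 without SS13BN 2. The share of chromosome 13 captures within 1 Mb, leaving out 10 kb, was 6.54% ± 0.0355 (SD, n = 2) in SS and 5.67% ± 1.44 (SD, n = 2) in SS13BN, with an exact permutation p of 1. This share cannot show a strain difference or its absence. At least 96.1% of fragments were captured in every distance class within 1 Mb in every library, so the share follows the library's total on chromosome 13. SS13BN 2, at 4.65%, was the lowest because it captured 9414 fragments of the chromosome, against 6538 to 6758 in the others, and without it the difference turned to 0.148 percentage points. Of the region's reads outside 10 kb, 84.6% ± 2.49 (SD, n = 2) in SS and 81.3% ± 5.70 (SD, n = 2) in SS13BN lay within 1 Mb, a measure added after seeing the data, with an exact permutation p of 0.667. This difference of -3.32 percentage points turned to 0.716 without SS13BN 2, and it was -0.900 with the fragment of shifted value left out. The distant zone held 26.4% ± 3.93 (SD, n = 2) of reads in SS and 24.0% ± 3.17 (SD, n = 2) in SS13BN, with an exact permutation p of 0.667. The smallest p that 2 against 2 libraries allow is 0.333.

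No fragment within 1 Mb of the viewpoint and no 50 kb window of chromosome 13 passed the test between strains. Of 446 fragments tested with limma, 0 passed adjusted p 0.05 and 0 had an unadjusted p under 0.05, where chance gives 22.3. In this test the difference between replicate numbers counts as spread within strains, and it was larger than that between strains. The median absolute log2 difference was 0.957 by number and 0.344 by strain. With replicate number as a block, 25 fragments had an unadjusted limma p under 0.05 and 0 passed adjusted p 0.05. Without the block, the fragments with the smallest p were those that start at 56513548, 55458500 and 55316615. The first had 3 and 26 reads in SS 1 and SS 2 against 34 and 57 in SS13BN 1 and SS13BN 2, a log2 difference (SS13BN minus SS) of 2.83 (SE 1.23; limma adjusted p = 1.0). The fragment at 55458500 differed by 2.29 (SE 1.03) and that at 55316615 by 1.25 (SE 0.66), with the same adjusted p. Of 1995 windows of 50 kb, 0 passed adjusted p 0.05 with limma, and 54 had an unadjusted p under 0.05, where chance gives 99.8. The smallest p belonged to the windows at 62400001, 2050001 and 61950001, each with limma adjusted p = 0.963. The window at 62400001 had 0 captured fragments in both SS libraries and 7 and 5 of 20 in SS13BN 1 and SS13BN 2. The window at 61950001 likewise had 0 in SS, and 3 and 5 of 27 in SS13BN. The window at 2050001 had 5 captured fragments of 17 in each SS library and 1 in each SS13BN library.

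For 50 kb windows, the tests had little reach. The median 95% half-width of the log2 difference was 1.19 for these windows and 2.02 for the near fragments, and a simulated 4-fold change was not called in any of 200 windows. Without SS 2, 8 windows passed, and without SS13BN 1, 38 passed, in fits that leave 1 library in a strain and assume that it varies like the others.

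Contact windows of chromosome 13, above a distance curve pooled over both sides, were few at 50 kb, and their number depended on the rule used. At 50 kb, 1 window, from 75550001 to 75600000, was a contact window in SS, and 0 were in SS13BN. It had 14 and 13 of 19 fragments captured in SS 1 and SS 2, and 8 and 13 in SS13BN 1 and SS13BN 2. Simulated data gave 5 to 8 false windows in either strain at 50 kb, more than the 1 found, and of windows raised 3-fold only 16.0% were found in both strains. With single libraries left out, SS had 8 without SS 1 or without SS 2, and SS13BN had 11 without SS13BN 1 and 8 without SS13BN 2. Leaving out a library also loosens the rule from 2 libraries to 1, so these counts could only stay or rise. With log odds of capture, SS had 11 and SS13BN had 7. With 100 kb windows, 3 contact windows were found in each strain and all 3 were shared. They start at 75500001, 94100001 and 103600001, all on the side of higher coordinates. Far from the viewpoint that side had the higher capture, so its windows lie above a pooled curve more readily. The side of these windows therefore adds nothing to that difference, and local contacts cannot be told apart from it.

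On other chromosomes, both strains had contact windows that overlapped far more than chance gives. Of 5332 windows of 500 kb, 99 were contact windows in SS and 84 in SS13BN. They shared 38, where 1.56 would be shared by chance. With SS 3 left out, SS had 198, and with SS13BN 3 left out, SS13BN had 279 and the strains shared 82. Leaving out a library also loosens the rule from 3 libraries to 2, so these counts could only stay or rise. Chance here assumes that windows are alike, which fragment length and chromosome shift. With the expectation set by fragment length, 58 and 47 windows passed and 19 were shared, against 0.511 by chance. With the expectation set by chromosome, 63 and 48 passed and 22 were shared.

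The strongest shared window lay on chromosome 20, from 32000001 to 32500000. There, 43.4% ± 15.3 (SD, n = 3) of 89 fragments were captured in SS and 51.7% ± 19.5 (SD, n = 3) in SS13BN, 4.07 ± 1.07 (SD, n = 6) times each library's share. The window from 222500001 to 223000000 on chromosome 1 reached 3.57 ± 0.263 times (SD, n = 6), and that from 226000001 to 226500000 reached 3.02 ± 0.636 times. Windows on chromosome 1 that start at 264500001, 271500001, 227500001 and 170500001 reached 2.81, 2.88, 2.66 and 2.50 times. The window from 13500001 to 14000000 on chromosome 10 reached 2.97 ± 0.525 times (SD, n = 6). On chromosome 8, the windows at 48000001 and 62500001 reached 2.75 and 2.60 times, and on chromosome 9 the window at 97000001 reached 2.43 times. Of the shared windows named here, only that at 48000001 was no longer shared with the expectation set by fragment length. Chromosome 1 held 12 of the 38 shared windows, chromosome 3 held 7 and chromosome 8 held 5. By their window numbers, these would hold 4.13, 2.55 and 1.89.

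**Figure D3:**
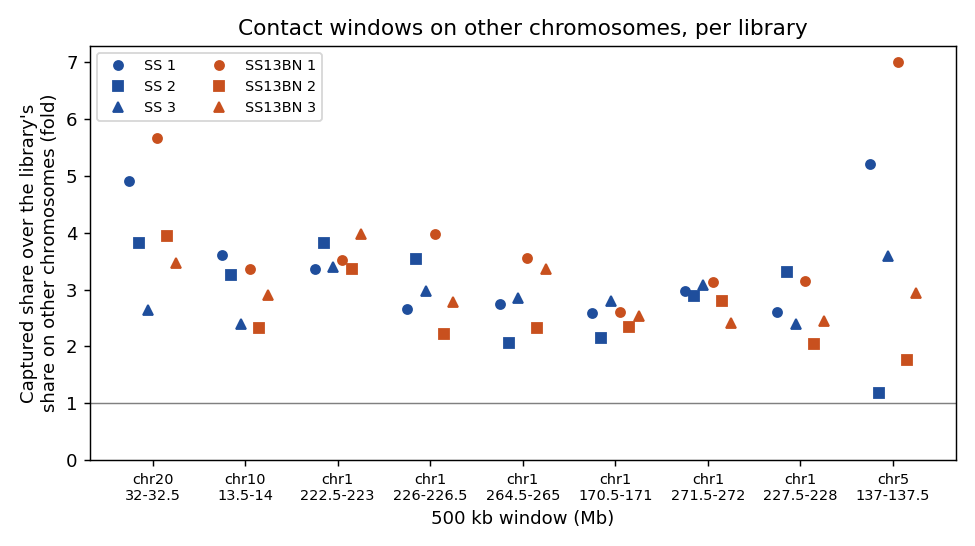
Captured share of 500 kb windows divided by the library's share over all chromosomes other than 13 (fold), for the shared windows among the 10 strongest of SS and for the chromosome 5 window found in SS13BN alone, 1 point per library (blue SS, orange SS13BN; circle, square and triangle for replicates 1, 2 and 3). In the shared windows every library lies above 2, and on chromosome 5 the libraries spread from 1.19 to 6.99.

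Most windows found in one strain alone passed in 2 libraries of the other. Of 61 windows of SS alone, 46 passed in 2 libraries of SS13BN, 14 in 1 and 1 in 0. Of 46 windows of SS13BN alone, 33 passed in 2 libraries of SS, 13 in 1 and 0 in 0. The strongest of SS alone were on chromosome 3 at 102000001, 14000001 and 101500001, and on chromosome 7 at 120000001 and 120500001. Each of these failed in SS13BN 3, the library with the fewest captured fragments, and that at 120000001 also failed in SS13BN 1. In SS13BN 3 only 174 windows passed, against 446 in SS13BN 1, 645 in SS13BN 2 and 472, 365 and 286 in SS 1 to 3. On chromosome 3 at 102000001, 35.9% ± 4.77 (SD, n = 3) of fragments were captured in SS and 34.9% ± 17.9 (SD, n = 3) in SS13BN. The strongest of SS13BN alone were on chromosome 5 at 137000001, chromosome 4 at 59000001, chromosome 19 at 65500001, chromosome 1 at 142000001 and chromosome 9 at 41500001. The chromosome 5 window had 39.6% ± 26.4 (SD, n = 3) captured in SS and 41.9% ± 23.9 (SD, n = 3) in SS13BN. Not all libraries that failed in the windows named here were near the threshold. Their binomial adjusted p ran from 0.0508 in SS 2 on chromosome 4 to 0.884 in SS 2 on chromosome 5. In all, 107 windows were found in 1 strain alone, and the 9 other splits of the libraries into 3 and 3 gave 107 to 164.

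No 500 kb window differed between strains in the limma test. Of 5296 windows, 0 passed adjusted p 0.05, and the smallest adjusted p was 0.999. An unadjusted p under 0.05 was found in 160, where chance gives 264.8. The strains were separated in 7.80% of windows, where chance gives 10.0%. The window with the smallest p, on chromosome 9 from 50500001 to 51000000, had 10, 6 and 14 captured fragments of 162 in SS and 23, 21 and 16 in SS13BN. Its log2 difference was 0.98 (SE 0.29; limma adjusted p = 0.999). The next were chromosome 1 at 128500001, with a log2 difference of 0.74 (SE 0.23), and chromosome 8 at 101500001, with 0.97 (SE 0.31), at the same adjusted p. The median 95% half-width was 0.51 on the log2 scale. In simulated data, 54.0% of windows changed 2-fold were called, and 5% of those changed 1.5-fold.

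Whole chromosomes took the same shares in both strains within the spread between libraries. Of 20 chromosomes, 0 passed adjusted p 0.05 with limma, and 0 had an unadjusted p under 0.05. The median 95% half-width of the difference was 0.06 on the log2 scale. Chromosomes themselves differed. Relative to each library's overall level, capture was highest on chromosome 16, at 1.27 ± 0.0306 (SD, n = 6), chromosome 10, at 1.24 ± 0.0487 and chromosome 3, at 1.21 ± 0.0173. It was lowest on chromosome 14, at 0.807 ± 0.0163, and on chromosome X, at 0.748 ± 0.0219. Male cells carry a single X, and cells of both sexes were pooled. Capture also varied with fragment length, whose median was 1960 bp on chromosome X and 2513 bp on chromosome 10. It was 2505 bp on chromosome 12, where relative capture was 1.01. How far copy number or fragment length enters these differences was not tested.

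Libraries of one strain were no more alike than libraries of different strains. Over 500 kb windows, Spearman correlations averaged 0.716 ± 0.0279 (SD) for the 6 pairs within a strain and 0.750 ± 0.0260 for the 3 pairs with the same replicate number in different strains. The other 6 pairs averaged 0.723 ± 0.0393. Near the viewpoint the contrast was sharper. Over 444 fragments within 1 Mb, read numbers correlated at 0.913 between SS 1 and SS13BN 1 and at 0.919 between SS 2 and SS13BN 2, against 0.740 between the SS libraries and 0.706 between the SS13BN libraries. The other pairs stood at 0.710 and 0.728. These correlations are across windows or fragments, which are not independent replicates.

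**Figure D4:**
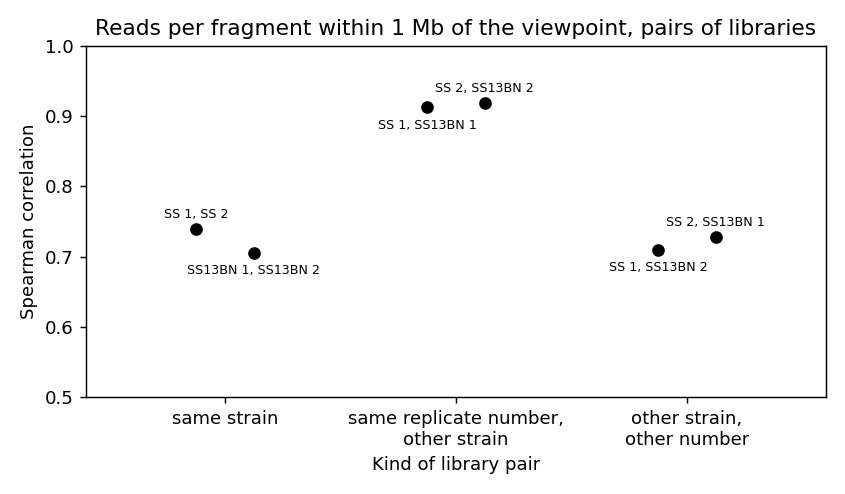
Spearman correlation of reads per fragment within 1 Mb of the viewpoint for each pair of scored libraries, by kind of pair; the axis starts at 0.5. Pairs with the same replicate number in different strains lie at 0.913 and 0.919, and all others between 0.706 and 0.740.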

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

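The bound used here was chosen after the tables were seen. SS 3 and SS13BN 3 entered no comparison on chromosome 13, because their scores there are listed at 0, yet their tables show that reads were counted near the viewpoint. Between 52028242 and 58275224, neighbouring fragments without reads share a row, and no 2 adjacent rows at 0 occur in the scored libraries. If the same merging was used, at least 583 of 1464 fragments (39.8%) were captured in SS 3 and at least 616 (42.1%) in SS13BN 3. At most 1071 (73.2%) and 1128 (77.0%) were captured. The scored libraries had 1225 (83.7%), 1293 (88.3%), 1249 (85.3%) and 1261 (86.1%) captured fragments in SS 1, SS 2, SS13BN 1 and SS13BN 2, above both upper bounds.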

How the results depend on the processing

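Each result was rerun under the alternatives, and the cause of the changes named here was not tested. The difference in the chromosome 13 share ran from -0.855 to 0.592 percentage points with single libraries left out, and it changed direction without SS 2 (0.592) and without SS13BN 2 (0.541). The difference in the share within 1 Mb ran from -1.88 to 0.148 and changed direction without SS13BN 2. That in near-region reads ran from -7.35 to 0.716 and changed direction without the same library. With the listed value of the SS13BN 2 fragment it was -1.90, and with that fragment left out -0.900.

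Windows of chromosome 13 past adjusted p 0.05 with limma numbered 0 to 38 with single libraries left out, 8 without SS 2 and 38 without SS13BN 1. The other window, fragment and chromosome tests gave 0 calls under every alternative. With the replicate number as a block, all 4 tests gave 0 calls, and unadjusted p was under 0.05 in 92 windows of chromosome 13, 203 windows elsewhere, 25 near fragments and 1 chromosome. Without the block, 0 near fragments had an unadjusted p under 0.05. Pairing by number was taken as shown only if, over at least 3 pairs, every correlation of deviations from the strain means exceeded 0.1. This rule was written after the results were seen, whereas the test without a block was planned as the main one. On the other chromosomes, the only data with 3 pairs, the correlations were 0.0875, 0.130 and 0.0834, so the block stayed an alternative. Yet every library's deviations there correlated best with those of its own number. By Spearman correlation of the windows themselves, the closest library had the same number for only 3 of 6 libraries, and by the odds ratio of capture for 4 of 6. With 2 pairs they were 0.124 for windows of chromosome 13 and 0.638 for near fragments, so for near fragments the data hint at pairing.

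For contact windows on chromosome 13 in SS, SS13BN and both, there were 0, 0 and 0 with residuals above 3, 3, 3 and 3 at 100 kb, 15, 19 and 5 with 1 of 2 libraries required, and 11, 7 and 1 with log odds. Leaving out single libraries gave 1 to 8, 0 to 11 and 0 to 1. On other chromosomes there were 43, 19 and 9 at adjusted p 0.01, 286, 329 and 184 with 2 of 3 libraries, and 156, 141 and 88 at 1 Mb. By fragment length there were 58, 47 and 19, and by chromosome 63, 48 and 22. Leaving out single libraries gave 99 to 198, 84 to 279 and 38 to 82. For contact windows, fewer libraries must pass when a library is left out, so such counts could only stay or rise. The mean correlation within strains was 0.796 at 1 Mb and 0.597 at 200 kb. Of 90 alternative values for named windows, 1 passed adjusted p 0.05. Gene lists, other count scalings and a filter on counts per feature were not run.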

Other observations

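All tests in this part were chosen after the results they concern were seen, except the limma tests by strain, which were planned. Capture outside chromosome 13 was far from random among fragments. In all 6 libraries, 11271 fragments were captured, where independent capture would give 1.69, and 478471 fragments were captured in none. Capture also rose with fragment length, from 3.72% of fragments up to 100 bp to 17.3% of those between 6400 and 12800 bp, and stood at 7.22% above 25600 bp. Of the longest class, 3.03% were captured in all 6 libraries and 0.746% in 1 library alone.

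The zone 0.4 to 0.7 Mb below the viewpoint ended sharply in the replicate 1 libraries and more gradually in the replicate 2 libraries. From the 100 kb bin at 54770181 to that at 54870181, mean reads per fragment went from 93.5 to 687 in SS 1, from 424 to 1026 in SS 2, from 120 to 577 in SS13BN 1 and from 144 to 317 in SS13BN 2. Adjacent shared contact windows on other chromosomes formed 5 runs of 1 Mb, 2 of them on chromosome 1, and 1 each on chromosomes 3, 8 and 16.

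One window of chromosome 5, from 137000001 to 137500000, varied most between libraries among 5312 windows, of which 14 varied past adjusted p 0.05, at 5.21, 1.19 and 3.58 times the library's share in SS 1 to 3 and 6.99, 1.76 and 2.94 times in SS13BN 1 to 3. After scaling to each library's share, the chi-square between libraries was 135, against a median of 4.05. Such scaling does not wholly remove depth, because a captured fragment counts once however many reads it has. Yet SS 2 and SS13BN 1, with like captured shares of 9.99% and 9.92%, stood at 1.19 and 6.99 times. This argues against depth, or a fixed property of the window's fragments, as the whole cause. The variation was not confined to this window. The windows of chromosome 5 at 135500001 and 137500001 ranked next, at 46.8 and 46.5, each with replicate 1 highest in both strains. Other windows among the 10 most variable, also past adjusted p 0.05 by chi-square, went both ways. The highest library had the same number in the 2 strains at 6500001 and 78000001 on chromosome 18 and at 39000001 on chromosome 11. It had different numbers at 6000001 and 28000001 on chromosome 18, 7500001 on chromosome 6 and 208500001 on chromosome 1. In the window at 137000001 the strains overlapped (exact two-sided permutation p = 0.9, where 0.1 is the smallest possible), which argues against strain as the whole cause. Shared handling of same-numbered libraries may contribute, since same-numbered pairs differed by 0.43 on the log2 scale, the lowest of 6 ways to match the libraries, too few to set coincidence aside.

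Near the viewpoint, libraries of the same replicate number resembled each other more than libraries of the same strain. With each library thinned to 108188 reads, the lowest correlation of same-numbered pairs was 0.915, so depth does not account for it. The highest same-strain correlation was 0.734, which restates the pattern and is no separate test of strain. Same-numbered pairs join different strains, so strain is not what they share. Shared handling of same-numbered libraries, or reads exchanged between them, may underlie it, but the labels name no batch, and on other chromosomes their deviations correlated weakly, though positively in all 3 pairs, at 0.0875, 0.130 and 0.0834. Grouped by number, 76 of 446 near fragments passed adjusted p 0.05 with limma, against 0 by strain and 0 in the crossed grouping, a count that restates the likeness of same-numbered libraries and is no separate test of it.

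One fragment of chromosome 13, from 57407684 to 57425902 and 1.85 Mb from the viewpoint, stood alone with 2054, 2863, 1449 and 9727 reads in SS 1, SS 2, SS13BN 1 and SS13BN 2. Its reads were at least 74.4 times the median of 10 flanking fragments. This was the highest ratio of 1006 fragments compared, all beyond 1 Mb from the viewpoint, and above the next, at 21.3. A contact domain that takes in the neighbours would raise them too, so the ratio argues against one. The fragment is 18219 bp long, against a median of 2189 bp on other chromosomes. A contact confined to it would leave the neighbours low and was not tested. In SS13BN 2 the deposited score was 13.3, and a shift of exactly 14.0 brought the SD of all scores from 0.741 to 1.0 and gave whole reads, which suggests that this value was altered after scoring. No other biological explanation was tested, and a sequence that attracts reads from elsewhere in the genome stays open.

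A further hypothesis was that of SS reads lost to mismatches with a BN reference on chromosome 13. It predicts fragments without reads in both SS libraries and with at least 10 in both SS13BN libraries. Among 1464 fragments between 52028242 and 58275224 there were 0, and 1 the other way round, as in the crossed grouping, while grouping by number gave 4 and 2. The absence of any such fragment argues against complete losses there. Farther out it was not tested, and there the windows at 62400001 and 61950001 had 0 captured fragments in both SS libraries and 7 and 5, and 3 and 5, in SS13BN, as such losses might give. Partial losses were not tested.

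The 6 libraries can be split in 10 ways, too few for a share under 0.05. Split by strain, 0 windows of 500 kb and 0 chromosomes passed adjusted p 0.05 with limma, and the highest counts of the other splits were 3 windows and 1 chromosome. Unadjusted p was under 0.05 in 160 windows by strain and in 171 to 347 in the other splits.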
